A study of Mus musculus with 22 samples.

How the data were processed

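The series profiled E2F3a, a member of the E2F family of transcription factors, on chromatin of the mouse nucleus accumbens (NAc) with CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA that a protein occupies. Per the labels' protocols, female and male mice received saline or cocaine at 20 mg/kg for 7 days, bilateral 12-gauge punches of the NAc were taken, and nuclei were incubated with an E2F3a antibody at 1 in 50 or a control immunoglobulin G (IgG) at 1 in 100. The labels list 7 cocaine E2F3a libraries (2 female, 5 male), 4 saline E2F3a libraries (2 female, 2 male), 4 cocaine IgG libraries and 5 saline IgG libraries. For 2 further IgG libraries the title and the treatment label name different treatments, so they were left unassigned and entered no comparison. The IgG libraries were not analysed here on their own, so no background from IgG stands beside the values.

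The authors deposited 1 peak list per treatment, with both sexes pooled per the file headers and names, so peaks could not be compared between replicates. Each peak has a fold enrichment (a ratio over the background of the peak caller) and the −log10 of its p and q, all computed by the authors, and the largest q in the deposited lists was 0.01. The authors also deposited a table of differential sites from diffReps with a negative binomial test. Its log2 fold changes, p-values and adjusted p-values are the authors' own, as are the mean normalized signal of each group and its enrichment ratio over a background that is not given in the sources used here. Per the submitters' processing notes the build is mm10. The aligner, the caller's settings, the version of diffReps and the use of the IgG libraries are not given in the sources used here.

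The deposited table also gives a normalized count for each library, joined within a cell, for 6 cocaine and 4 saline libraries. These values carry no library names, so which of the 7 labelled cocaine libraries was left out, and the sex of each value, are not known. The libraries are called cocaine 1 to 6 and saline 1 to 4 in the order of the table, which is not the replicate number of the labels. Within a library the values were whole multiples of 1 step, the normalized count worth 1 read. Of the values up to 20 reads, 100.0% came out whole within 0.1 step in each library. The step ran from 0.64 to 2.21 in cocaine and from 0.38 to 1.88 in saline, and a larger step stands for fewer reads at the same normalized count. Total recovered reads at the called sites did not always follow it. Cocaine 6 had a step of 1.71 and 102377 reads, and cocaine 1 a step of 0.64 and 90283 reads. Depth is weighed below through the step. Total depth is not known, since the table holds only called sites. None of the 21 pairs of libraries within a group held identical values, and chi-square per degree of freedom of their recovered reads ran from 1.94 to 15.1, above sampling noise. The labels do not say that each library came from a separate animal, so p-values computed from library values measure the spread between libraries. The binomial, Fisher, placement, gene list and fold enrichment tests take sites, peaks or genes as units. Their p-values measure no spread between libraries.

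Sites with an adjusted p below 0.05 in the authors' table were used. The split of directions was tested with an exact binomial test, genomic features and gene lists with Fisher's exact test and Benjamini-Hochberg adjustment, and overlaps with 1000 random placements on the same chromosome, starting at 3000000 bp, one-sided and without a map of unmappable sequence. Peaks on unplaced sequence were left out of placements. Gene lists were compared with 10000 random sets of protein-coding autosomal genes matched on length in 20 bins, one-sided. Medians of fold enrichment were compared by a permutation test with 100000 resamples, two-sided. Named sites were tested with an exact permutation test of the mean over all 210 splits of the 10 libraries, two-sided, whose smallest p is 0.0095. These sites were selected by the authors on the same libraries, so that p describes the overlap of libraries and is not independent evidence. Added after the data were examined, limma was run on log2(normalized count + 1) over the called sites, and a quasi-Poisson test on the recovered reads. A fold change on that scale understates the change at low sites. For the counts over 100 splits of the libraries, limma was fitted to the higher sites alone and to the lower sites alone and adjusted within each, so those counts differ from the fit to all called sites. The median log2 ratio of each cocaine library was fitted to its log2 step by least squares and the slope compared with the group difference in mean median divided by that in mean log2 step. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

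Before the data were examined, 13 gene lists and a rule for named items were fixed. The rule took the 12 genes with the smallest adjusted p in each direction at a promoter or gene body, without genes of the Gm-number or Rik kind, ties going to the larger log2 fold change, and the 10 peaks with the highest fold in each of 3 sets. It also took up to 4 members of each list with a called site, and E2f3. An item that the rule names is not reported here. A site within an intron or exon of a gene other than the one the table names was passed over, a reading of the rule made after the data were seen. Gene identifiers of 952 of the 956 sites (99.6%) matched the gene table used, of the same build (mm10). That table gives no strand, so the planned share of peaks near transcription start sites was replaced by the share within 1 kb of either end of a protein-coding gene, and peaks were named by the nearest gene. The planned motif search needs a genome sequence and was not run. The planned test of sites on sex chromosomes had no sites to test, and peaks on X and Y were compared instead. Older histone names in the list were matched through synonyms, and 64 genes were found for its 70 names, some of which name the same gene.

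On simulated data with 200 of the 947 sites changed, limma recovered 42 of 100 sites changed 2-fold and 85 of 100 changed 3-fold and called 4 of 747 unchanged sites. That simulation gave every library the same spread beyond sampling noise and did not select sites for a group difference. The real sites were so selected, and cocaine libraries spread more at higher sites, so these rates need not hold for the data. The quasi-Poisson test recovered 29 of 200 sites changed 2-fold and called 4 of 747 unchanged. The placement permutation test gave p = 0.305 with no planted overlap and p = 0.001, the smallest 1000 placements can give, with 140 planted. Alternatives covered overlap rules, peak and site thresholds, list length, low counts, autosomes, the other sheets of the table and leaving out each library. Added after the data were examined were leaving out the 2 cocaine libraries with the largest step, a pseudocount of 0.5, the quasi-Poisson test, 1 site per run of neighbouring sites and the gene lists among peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.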

Results

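E2F3a occupancy was profiled by CUT&RUN in the NAc, a striatal region involved in reward, of mice given cocaine at 20 mg/kg or saline for 7 days. The deposited values comprised 3467 peaks for cocaine and 725 for saline, each list pooled over both sexes, and 956 sites that the authors listed as different, with a normalized count for each of 6 cocaine and 4 saline libraries. Coordinates are mm10. Across the 947 called sites, recovered reads per library ran from 46136 to 102377 in cocaine and from 41102 to 152186 in saline. The median per listed site was 13 to 25 reads in the cocaine libraries and 14 to 48 in the saline libraries.

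The comparison of the peak lists asked where E2F3a was found after each treatment. Most of the saline peaks lay in regions that were also in the cocaine list. The shared regions with the highest fold enrichment included regions at Prkdc, which encodes a DNA repair kinase, and Dlg4, which encodes a postsynaptic scaffold. Another lay 261 bp from Mcm5, which encodes a subunit of the replicative helicase. Cocaine peaks without a saline counterpart included Slbp, which encodes the protein that binds histone mRNA, the splicing factor gene Srsf1 and the DNA methyltransferase gene Dnmt1. Of the 701 saline peaks on assembled chromosomes, 538 (76.7%, 95% interval 73.4 to 79.8) overlapped a cocaine peak by at least 1 bp, against a mean of 1.14 when positions were permuted (random placement permutation p = 0.001, the smallest 1000 placements can give). In the full lists, 545 of the 3467 cocaine peaks (15.7%) overlapped a saline peak. With the cocaine list trimmed to the length of the saline list, 44.4% of saline peaks overlapped.

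Fold enrichment is the authors' value for each peak and was compared within a list. A peak said to be in a gene was 0 bp from it, and may lie at its end rather than in its body. Among cocaine peaks that overlapped a saline peak, the highest were in Prkdc (chromosome 16, 15637370 to 15638223, 43.2-fold), Dapk1 (chromosome 13, 60680979 to 60682133, 42.8-fold), Ttc34 (35.8-fold) and Rccd1 (25.9-fold). Peaks in Dlg4 (19.2-fold) and Fbxl19 (18.0-fold) and 261 bp from Mcm5 (chromosome 8, 75108621 to 75109389, 17.9-fold) were also among the 10 highest, with peaks nearest to Nudt12, Gm45988 and Ccr1. Among cocaine peaks that overlapped none, the highest were in Zfp868 (25.6-fold) and Vrk3 (16.4-fold), with Slbp at 16.0-fold (chromosome 5, 33652080 to 33652805), Srsf1 at 15.6-fold (chromosome 11, 88047003 to 88047998) and Dnmt1 at 15.0-fold (chromosome 9, 20952561 to 20952896). The other peaks of that set were nearest to Tmem121, Mid1, Ccdc191, Higd2a and Enpp5. Among saline peaks that overlapped none, Scyl2 (10.5-fold) and Lrrc49 (9.88-fold) were highest, followed by peaks nearest to Manea, Cd180, Thoc6, Atp8a2, Plac8, Ahnak, Ttc41 and Gm20795 at 6.31-fold to 6.94-fold. Within the cocaine list the median fold was 5.82 at shared and 4.84 at unshared peaks, and within the saline list it was 3.60 and 4.34 (permutation p = 1e-05 in each list, the smallest 100000 resamples can give). The difference within the saline list was -0.74, and it was -0.10 with a permutation p of 0.5 when sharing needed 50% reciprocal overlap.

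Peaks of both lists lay near the ends of protein-coding genes more often than random positions did. A summit within 1 kb of a gene end was found for 963 of 3435 cocaine peaks (28.0%, 95% interval 26.5 to 29.6) and 148 of 701 saline peaks (21.1%, 18.1 to 24.3), against 3.12% and 3.08% at random positions. The odds ratio of cocaine to saline was 1.46 (Fisher's exact test, two-sided, p = 0.00015, with peaks as units). On X lay 169 cocaine peaks (4.92%) and 51 saline peaks (7.28%), with an adjusted p of 0.016 in Fisher's exact test, and on Y 38 (1.11%) and 18 (2.57%), with an adjusted p of 0.012. The labels list 2 female and 5 male cocaine E2F3a libraries, and 2 female and 2 male saline ones. More males in cocaine go with a lower X share there, but not with a lower Y share. Which libraries were pooled is not known, and the cause was not tested. E2f3 itself (chromosome 13, 29906575 to 29986064) carried no peak and no called site. The nearest cocaine peak was 834.7 kb away and the nearest saline peak 1550.1 kb away.

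The differential sites addressed which regions gained or lost E2F3a signal after cocaine. Sites that were lower in cocaine lay mostly at promoters and in introns, and included the promoters of Brd2, which encodes a reader of acetylated histones, Hdac4, which encodes a histone deacetylase, and Slc4a2, which encodes an anion exchanger. Sites that were higher lay most often between genes, and the higher sites near genes included Fasn, which encodes fatty acid synthase, and Smg5, a factor of nonsense-mediated mRNA decay. In the authors' deposited table, 474 sites were lower and 473 higher at an adjusted p below 0.05, an even split (exact binomial p = 1.0). That test took sites as units, although neighbouring sites are not independent. With sites less than 100 kb apart joined, there were 444 lower and 264 higher regions, so by region the split was not even. With an absolute log2 fold change of at least 1, 40.3% of sites were higher, and among sites that overlapped a peak 76.2% were.

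Promoter sites within 1 kb of a transcription start site, by the authors' annotation, made up 191 of the 474 lower sites (40.3%, 95% interval 35.8 to 44.9). They made up 72 of the 473 higher sites (15.2%, 12.1 to 18.8). The odds ratio was 3.76 (Fisher's exact test with sites as units, adjusted p = 2.4e-17). Distal intergenic sites showed the opposite split, with 102 lower (21.5%) and 216 higher (45.7%, adjusted p = 8.4e-15). Introns held 125 lower and 92 higher sites (adjusted p = 0.02), and exons 21 lower and 44 higher (adjusted p = 0.0061). The split passed no threshold for promoters at 1 to 3 kb (30 lower, 36 higher, adjusted p = 0.45) or for untranslated regions (5 lower, 13 higher, adjusted p = 0.073).

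**Figure D1:**
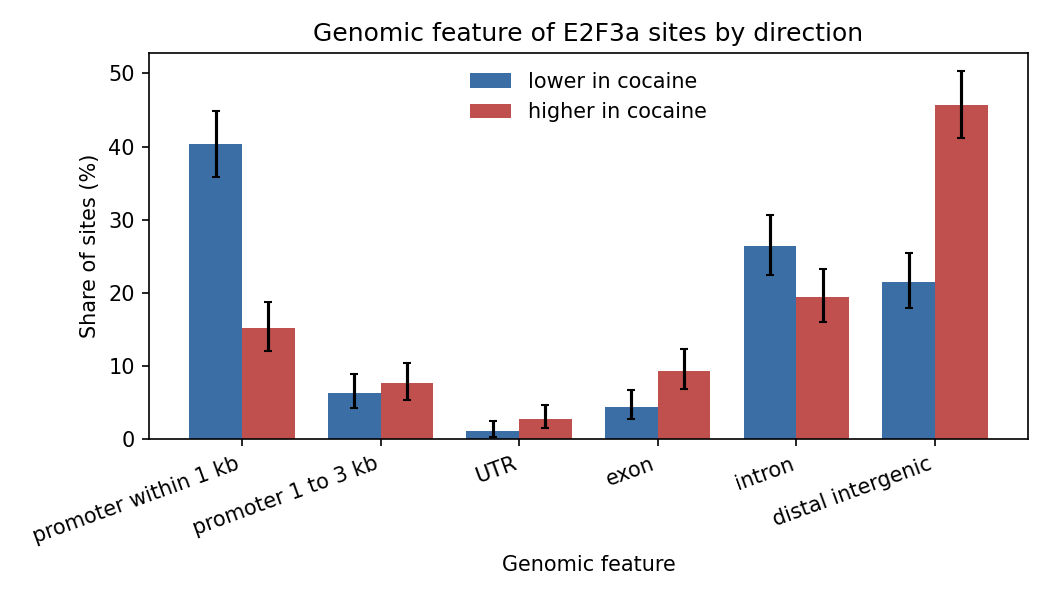
Share of called E2F3a sites (%, vertical axis) in each genomic feature, for 474 sites lower and 473 sites higher in cocaine, with exact 95% intervals as error bars. Promoters within 1 kb hold 40.3% of lower and 15.2% of higher sites, and distal intergenic sequence 21.5% and 45.7%.

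At the named lower sites the 6 cocaine libraries lay below the 4 saline libraries. The promoter site of Brd2 (chromosome 17, 34119502 to 34120500) had a normalized count of 98.6 ± 10.3 (SD, n = 6) in cocaine and 131.1 ± 11.6 (SD, n = 4) in saline, and that of Gt(ROSA)26Sor (chromosome 6, 113076002 to 113077100) 40.8 ± 8.48 and 71.7 ± 6.25. At Hdac4 (chromosome 1, 92178302 to 92179500, promoter) the counts were 11.5 ± 6.79 and 26.6 ± 4.03, and at Slc4a2 (chromosome 5, 24424602 to 24426100, promoter) 13.9 ± 4.77 and 35.6 ± 6.15. Counts were lowest at an exon of Tmtc3, with 1.47 ± 2.08 in cocaine and 13.2 ± 5.15 in saline, and at the promoter of Slk, with 2.04 ± 2.96 and 14.8 ± 6.54. The other named lower sites were at the promoters of Nek1, Tnrc18, Pan2 and Clstn1 and in introns of Adk and Asap1. In the authors' deposited table the log2 fold changes of these 12 sites ran from -3.17 at Tmtc3 to -0.26 at Tnrc18. The exact permutation p was 0.0095, the smallest the design allows, at 12 of the 12. The authors' enrichment over background was not lower in cocaine at Brd2 (3.93 against 3.88 in saline), Nek1 (3.37 against 2.92) and Tmtc3 (4.16 against 2.95), so there the 2 measures disagree. The Brd2 site also overlapped a cocaine peak and no saline peak. The Tnrc18 site overlapped a peak of each list, and the other named lower sites overlapped none.

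The named higher sites had a wider spread between cocaine libraries. At Fasn (chromosome 11, 120821002 to 120822000, 1780 bp from the transcription start site) the normalized count was 20.5 ± 6.73 (SD, n = 6) in cocaine and 7.26 ± 0.96 (SD, n = 4) in saline, and at Smg5 (chromosome 3, 88360102 to 88361100, promoter) 18.9 ± 9.54 and 4.56 ± 2.11. At Slc35e4 (chromosome 11, 3911802 to 3912900) it was 23.0 ± 9.10 and 8.36 ± 3.82, and at Cyria (chromosome 12, 12261102 to 12262500, promoter) 29.8 ± 13.5 and 11.3 ± 2.77. The exact permutation p was 0.0095 at Fasn, Smg5, Slc35e4 and Tcp10c, and passed 0.05 at 9 of the 12 sites. It did not at Mroh2a (58.3 ± 48.7 against 24.3 ± 7.19, exact p = 0.21), Trpm8 (37.3 ± 25.6 against 15.0 ± 3.24, exact p = 0.124) or an intron of Prkg1 (36.2 ± 36.0 against 10.3 ± 4.36, exact p = 0.057). The others were Dnah6, Rab6b, Smok2a and Sp140l2. Enrichment was not higher in cocaine at Trpm8 (0.71 against 0.76). Without cocaine 5 and 6 the log2 ratio fell from the authors' log2 fold change by over 1.5 times at Mroh2a (1.26 to 0.37), Trpm8 (1.32 to 0.54), Prkg1 (1.81 to 0.63), Dnah6 (1.51 to 0.66), Smok2a (1.30 to 0.76) and Tcp10c (1.70 to 1.12).

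**Figure D2:**
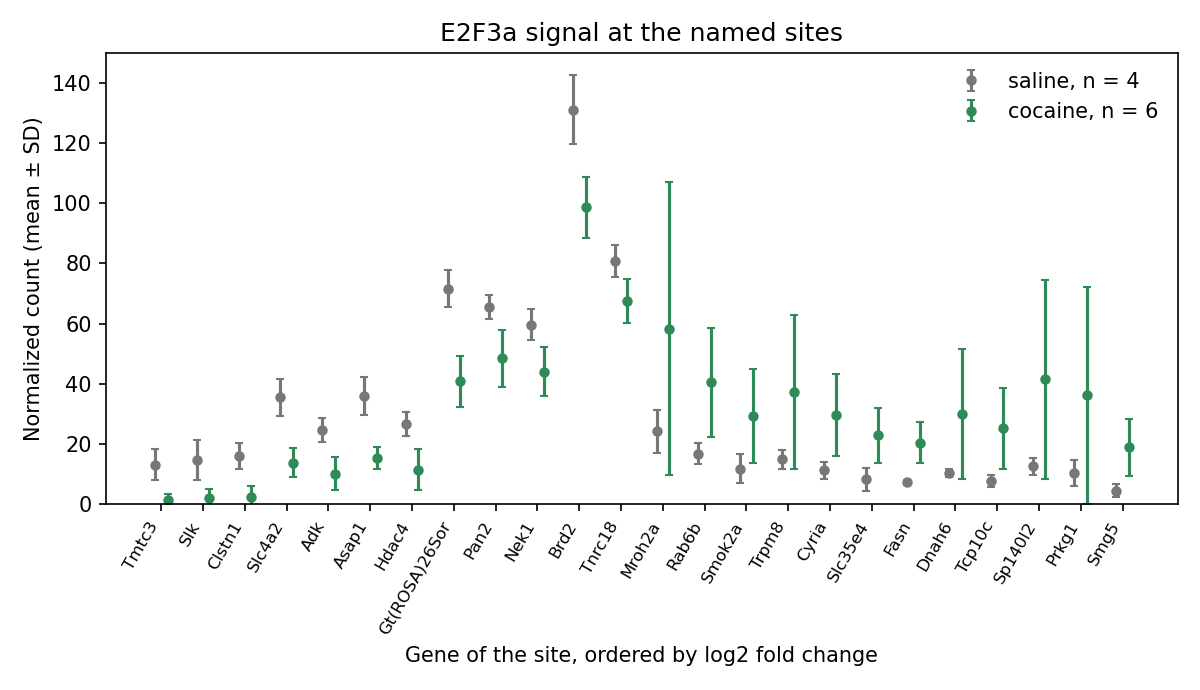
Normalized count (vertical axis, mean ± SD) at the 24 sites named by rank, ordered by the authors' log2 fold change, for 4 saline (grey) and 6 cocaine (green) libraries. Cocaine libraries spread more at sites higher in cocaine, as at Mroh2a (58.3 ± 48.7), than at lower sites such as Brd2 (98.6 ± 10.3).

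Lower sites fell by a median of 1.14 on the log2 scale (quartiles -1.37 and -0.93) and higher sites rose by a median of 0.97 (0.84 and 1.17) in the authors' deposited table. Median enrichment over background at lower sites was 2.59 in saline and 1.14 in cocaine, and it was lower in cocaine at 431 of the 474 (90.9%). At higher sites it was 0.78 in saline and 1.08 in cocaine, with a higher value in cocaine at 421 of the 473 (89.0%), and 81 (17.1%) reached 2 in cocaine. The groups did not overlap at 228 lower sites (48.1%) and 54 higher sites (11.4%), where chance gives 0.48% in a given direction at unselected sites. The authors chose the sites for differing between these libraries, so these shares are no test. The median log2 ratio to the saline mean at lower sites lay between -1.23 and -0.99 in the 6 cocaine libraries. At higher sites it lay between -0.23 in cocaine 2 and 1.90 in cocaine 5, and at 337 of these sites (71.2%) the highest 2 of the 10 values were cocaine 5 and 6, the cocaine libraries with the fewest reads per unit of count. Without cocaine 5 and 6, the median log2 ratio at higher sites was 0.36, 67 sites turned direction and 155 remained at least 1.5-fold higher, whereas 424 of the 474 lower sites remained at least 1.5-fold lower. Of the 81 higher sites with a cocaine enrichment of at least 2, 74 remained at least 1.5-fold higher (91.4%), against 81 of the 392 others (20.7%), and the share was 30 of 138 (21.7%) at higher sites that overlapped a cocaine peak and 32 of 199 (16.1%) at those in runs of 5 or more.

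**Figure D3:**
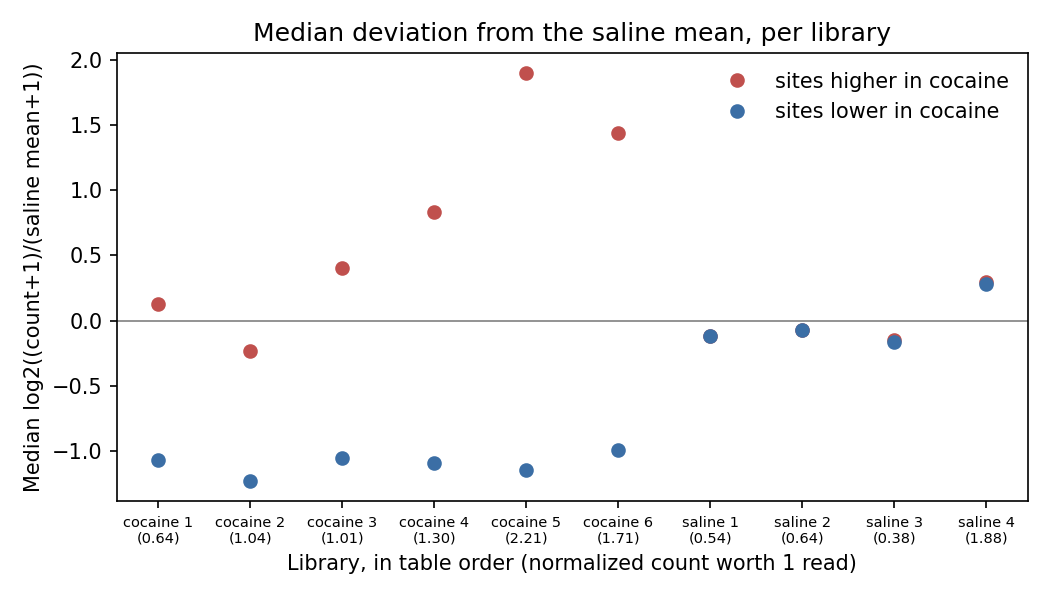
Median log2 ratio of the normalized count + 1 to the saline mean + 1 (vertical axis) in each of 10 libraries, at sites higher (red) and lower (blue) in cocaine, with the count worth 1 read in brackets. At lower sites the cocaine libraries lie between -1.23 and -0.99, and at higher sites between -0.23 and 1.90.

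Higher sites lay in runs along the genome. Of the 473 higher sites, 199 (42.1%) fell into 17 runs of 5 or more sites less than 100 kb apart, and none of the 474 lower sites did. The longest run held 36 sites at Potefam3a and Potefam3b (chromosome 8, 20282702 to 20705600). Others held 21 sites at Mroh2a, Trpm8, Hjurp and Ugt1a1 (chromosome 1, 88211802 to 88302700), 20 at Sfi1, Eif4enif1 and Pisd-ps1 (chromosome 11, 3126202 to 3200700), 14 at Snhg14 (chromosome 7, 59733302 to 59882400) and 12 at Zfp982 (chromosome 4, 147334502 to 147426600). Where genes of a run have near-identical copies, the alignment could have split or shared their reads, so values there are uncertain. The longest lower run held 4 sites at Bcl11a.

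Most called sites lay outside called peaks, and higher sites lay in peaks more often than lower sites. Of higher sites 138 (29.2%, 95% interval 25.1 to 33.5) overlapped a cocaine peak and 45 (9.51%) a saline peak, and of lower sites 36 (7.59%, 5.38 to 10.4) and 17 (3.59%). Random placements gave a mean of 1.27, 0.26, 1.13 and 0.21 (placement permutation p = 0.001 each, the smallest 1000 placements can give). The share in cocaine peaks differed between directions with an odds ratio of 5.01 (Fisher's exact test with sites as units, p = 1.9e-18). Higher sites were chosen for more signal in cocaine libraries, from which the cocaine peaks also come. The difference in share is therefore no independent support for the higher sites. The cocaine list was also the longer, and neighbouring sites in runs are not independent.

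By gene list, replication-dependent histone genes stood out among the lower sites. Of 64 histone genes 6 had a lower site and none a higher one, against a mean of 0.98 in length-matched sets for any site (adjusted p = 0.0026). These were H3c6 (23562602 to 23563700, promoter), H4c8 (23530802 to 23532700, promoter), H2bc23 (distal intergenic, 20931 bp from its transcription start site) and H2ac15, with H2bc4 and H2bc3. All lay within 21753202 to 23748200 on chromosome 13, so they are neighbours and not independent. The sites at H3c6 and H2bc3 overlapped a cocaine peak and no saline peak. Those at H4c8 and H2ac15 overlapped a saline peak and no cocaine peak, and the others overlapped neither. Without cocaine 5 and 6 the log2 ratio was -0.31 at H3c6 and -0.19 at H2ac15, against log2 fold changes of -0.67 and -0.43 in the authors' table. Synaptic adhesion and axon guidance genes had 14 of 65 members with a site, against a mean of 6.65 in length-matched sets (adjusted p = 0.027), 8 with a higher and 8 with a lower site. Higher sites were nearest to Ctnna2 and Tenm3, lower ones at the promoter of Magi2 and nearest to Cdh18. Without cocaine 5 and 6 the log2 ratio at higher sites fell to 0.03 at Ptprd, 0.04 at a distal intergenic site nearest to Csmd3 and -0.06 at one nearest to Cntn1. The authors' log2 fold changes there were 1.09, 0.53 and 0.77. At the other genes of the list with a higher site, the ratio without these libraries ran from 0.45 at Ctnna2 to 1.30 at Lrrtm1. Ctnna2 also had a lower site (log2 fold change -1.42 in the authors' table, log2 ratio -1.10 without cocaine 5 and 6), and the same values at its higher site were 0.88 and 0.45. The call of the synaptic adhesion and axon guidance list was lost with sites at a stricter adjusted p of 0.01 (adjusted p = 0.057 for the list). It was also lost with promoter and gene body sites alone (adjusted p = 0.37). None of the 13 lists differed between genes with higher and genes with lower sites (Fisher's exact test, smallest unadjusted p = 0.087, adjusted p = 0.95).

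The other lists did not pass against length-matched genes. RNA splicing factor genes had 5 members with a lower site and none with a higher one (adjusted p = 0.21), among them Celf2, Celf4, Qki and Rbfox3. Glutamate receptor and postsynaptic density genes had 3 higher (Camk2b, Dlgap1 and Dlgap2) and 3 lower (Grm3 first by adjusted p, then Grm7 and Shank1, adjusted p = 0.21). The Grm3 site was distal intergenic, at -302832 bp from the transcription start site. Chromatin regulators had 1 higher (Hdac9) and 4 lower, with Hdac4, Auts2 and Arid1a first (adjusted p = 0.25). Of the genes of medium spiny neurons, the main neurons of the NAc, Pde4d and Adcy5 were among those with a lower site. The Pde4d site was distal intergenic, 47490 bp from the transcription start site, and the Adcy5 site lay in an intron. The list as a whole did not pass (adjusted p = 0.54). Cell cycle and DNA replication genes had a lower site at Cdc6, which encodes a replication licensing factor, and a higher one nearest to Cdkn1a (adjusted p = 0.54). Immediate early and activity-regulated genes had a lower site nearest to Nr4a1 and a higher one in Creb1 (adjusted p = 0.54). Genes of GABA receptors had lower sites at Gabrg1 and Gabra2 (adjusted p = 0.54), and channel genes 1 higher (Kcnh1) and 3 lower (Kcnq3, Cacna1e and Cacna2d3, adjusted p = 0.54). Among markers of other cell types, the astrocyte gene Gpc5 (adjusted p = 0.54) and the oligodendrocyte gene Cnp (adjusted p = 0.58) had a higher site, and 0 of 20 microglia and vascular markers had a site. Of the list members named, the exact permutation p did not pass 0.05 at Dlgap2 (0.51), Cdkn1a (0.39), Gpc5 (0.33), Kcnh1 (0.15), Dlgap1 (0.11), Kcnq3 (0.076), Tenm3 (0.067) and Hdac9 (0.057). Without cocaine 5 and 6 the log2 ratio was -0.37 at Dlgap2, -0.09 at Cdkn1a, 0.0032 at Gpc5, 0.23 at Kcnh1, 0.40 at Dlgap1, 0.44 at Creb1, 0.54 at Hdac9 and 0.55 at Tenm3, where the authors' log2 fold changes ran from 0.64 to 1.23. Enrichment was not higher in cocaine at Cdkn1a (0.67 against 0.70).

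Run on the called sites, limma passed 63 higher and 294 lower sites at an adjusted p below 0.05, and 131 and 409 at an unadjusted p below 0.05. Without any 1 of the saline libraries limma passed 0 sites after adjustment in either direction, and without cocaine 4 it passed 0 higher and 2 lower, while 80 to 114 higher and 296 to 355 lower sites had an unadjusted p below 0.05 without a saline library. The quasi-Poisson test on recovered reads passed 80 higher and 334 lower sites. The authors chose these sites on the same libraries, so the limma and quasi-Poisson counts are no independent test of them.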

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

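The tests weighed here were chosen after the results were seen, apart from the overlaps of the peak lists, whose bounds were set afterwards and at first for the full list alone, and depth was weighed with 3 measures in turn, each chosen with the medians of each library known: the correlation with step, which left depth open in both directions, a count of libraries by step, which rested on saline 4, and the slope on step.

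Of 54 groups of values examined for a single library far from the rest, 4 stood out, where chance gives about 2.7. At Sp140l2, the highest cocaine library had a normalized count of 103.99 and the next 43.26. At Clstn1, the highest saline library had a normalized count of 22.55 and the next 14.12. Among the saline libraries, saline 4 had a median log2 ratio of 0.29 at higher sites, with the next at -0.08, and a step of 1.88, with the next at 0.64.

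Sites higher in cocaine drew most of their difference from cocaine 5 and 6. Whether reads shared between near-identical copies contribute was not tested. Depth may contribute and stays open, since the slope of the median on log2 step within cocaine was 1.13 (95% interval 0.27 to 1.99), where depth as the whole cause needs 0.96, but the interval held 0 without any 1 of cocaine 3 (slope 1.13), cocaine 4 (1.13), cocaine 5 (0.96) or cocaine 6 (1.08). The correlation gave rho = 0.829 between step and median log2 ratio over the 6 cocaine libraries (exact permutation p = 0.058, Pearson r = 0.92 with exact p = 0.017, adjusted p = 0.12 and 0.067 over 4 relations), but r was 0.55 and rho 0.40 without the 2 libraries farthest in step, so the relation rests on them. Gained E2F3a also stays open, since median cocaine enrichment was 1.08 over a background of unknown kind. Among 100 splits of the 10 libraries, with limma fitted to the higher sites alone, 8, the real one included, gave at least the real count of 108 sites at an unadjusted p below 0.05 (highest other 398 with cocaine 3 to 6 set apart), so chance cannot be excluded and the libraries have a structure other than treatment. Unadjusted p was used because in this fit, unlike the fit to all called sites, 0 higher sites passed after adjustment in the real split, against 391 in that other split.

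Sites lower in cocaine were low in each cocaine library, with the highest library median at -0.99, which argues against 1 or 2 libraries setting them. A general loss of signal over background would lower most enriched regions, but 2.43% of saline peaks (17 of them, 95% interval 1.42 to 3.85) overlapped a lower site. That argues against a loss large enough to be called at most saline peaks. A modest general loss stays open, since the power of the authors' test at these peaks is not known. The saline list also does not hold all enriched regions, since 378 of the lower sites (79.7%) had a saline enrichment of at least 2 and most lay outside it. Depth as the whole cause, in proportion to log2 step, needs a slope of -1.37, but the slope of the median on log2 step within cocaine was 0.00 (95% interval -0.18 to 0.18), which argues against it. Without each library in turn the slope needed ran from -2.29 to -0.78, the latter without saline 4, and lay outside the interval each time. The count gave 5 of the 5 cocaine libraries with a step in the saline range at least 1.5-fold lower, but without saline 4 none lay in that range, so it decided nothing, and neither did the correlation (rho = -0.143, exact permutation p = 0.80, n = 6). With limma fitted to the lower sites alone, the real split gave 420 sites at an unadjusted p below 0.05 and the highest other 161, so of the 100 splits 1, the real one, reached that count, but the authors chose these sites by the real split, so chance is neither excluded nor shown by this count. Less E2F3a at these sites after cocaine is a candidate explanation that was not tested apart from the groups.

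The cocaine list held 3467 peaks and the saline list 725. Of saline peaks 76.7% overlapped the full cocaine list and 44.4% (95% interval 40.6 to 48.1) that list at equal length, so different regions under each treatment stay open. More reads in the cocaine pool might add peaks. Taken as the inverse of the step, the relative reads of the 6 cocaine libraries were 0.81 times those of the 4 saline libraries. This is not a count of reads, and recovered reads at the sites did not always follow the step. Since the labels list 7 cocaine libraries and the reads pooled for peak calling are not known, depth and treatment cannot be told apart here.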

How the results depend on the processing

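Tests added after the data were examined are the limma and quasi-Poisson counts, the pseudocount, the runs and leaving out the 2 cocaine libraries with the largest step. Among the results that answer a comparison, 71 alternatives stayed the same, 22 were weaker, 3 stronger, and none reversed a called direction. A tested result stayed the same if it kept its side of the p threshold. A count stayed the same if it was within 1.5-fold of the main count. With an absolute log2 fold change of at least 1, higher sites numbered 217 and the share of higher sites was 40.3%. Among sites overlapping a peak there were 138 higher and 43 lower, a share of 76.2% higher, so the even split gave way in opposite directions. Without the 2 cocaine libraries with the largest step, 155 higher sites stayed at least 1.5-fold higher. With 50% reciprocal overlap the saline difference in median fold was -0.1. The lists with more members than length-matched genes fell from 2 to 1 at an adjusted p below 0.01 and to 1 with promoter and gene body sites. The cause was not tested in these cases.

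Leaving out each library in turn, limma passed 0 to 129 higher sites and 0 to 323 lower sites, where all libraries gave 63 and 294. The 0 counts came without any 1 saline library, and without cocaine 4 (0 higher, 2 lower). The median p of sites with a lower estimate was 0.014 with all libraries and 0.023 to 0.04 without a saline library. The cause of the drop to 0 was not tested. Without cocaine 5 alone the median log2 ratio of higher sites was 0.70, and 307 stayed at least 1.5-fold higher. Without cocaine 5 and 6 the log2 ratio of the 24 sites named by rank changed by more than 0.58 at 7, Tcp10c (0.581) and Tmtc3 (0.583) barely so, and by more than the SD between libraries (pooled within groups) at 2, Dnah6 and Prkg1.

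No paired analysis was possible because the values per library carry no replicate number. The motif alternatives and those of sex chromosome sites were not run. Depth limits sites with few reads, such as Tmtc3.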

Other observations

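The gene lists were also set against the peak lists, a comparison chosen after the data were seen, with 26 tests in all. Of 51 cell cycle and DNA replication genes known as E2F targets, 13 had a cocaine peak within 1 kb of a gene end, against a mean of 3.21 in length-matched sets (adjusted p = 0.0005), among them E2f1, Pcna, Mcm2, Mcm5, Rrm2 and Brca1. In the saline list 6 did, against 0.47 (adjusted p = 0.0005), with Ccna2, Chek1, Mcm4 and Mcm7 among them. Histone genes had a cocaine peak at 37 of 64 members, against 2.68, and a saline peak at 15, against 1.06 (adjusted p = 0.0005 each), although neighbouring histone genes can share a peak. RNA splicing factor genes had 15 of 53 in cocaine, against 3.20 (adjusted p = 0.0005), including Srsf1, Srsf2 and Hnrnpa1, and 4 in saline, against 0.43 (adjusted p = 0.003). Genes were matched on length and not on activity.

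Immediate early and activity-regulated genes had a cocaine peak at 9 of 35 members, against 2.13 (adjusted p = 0.0009), namely Arc, Crem, Dusp1, Egr1, Fosl2, Jun, Jund, Per1 and Per2. In the saline list Btg2 and Dusp1 had one, against 0.31 (adjusted p = 0.126), and the difference between the lists was not tested. Genes of medium spiny neurons had 1 of 42 in cocaine, at Gng7, against 2.45, and 0 in saline. No astrocyte, oligodendrocyte or microglia and vascular marker had a peak of either list within 1 kb of a gene end, and peaks within gene bodies were not counted. The remaining lists, of glutamate, GABA, adhesion, channel and chromatin genes, passed in neither (adjusted p of 0.29 or more).

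A list of 140 gene names stands beside the deposited table without a stated meaning. A hypothesis, tested after the list was seen, was that these genes carry more sites than genes of like length. Of the 103 that could be tested, 6 had a called site (higher at Slc35e4, and lower at Epc1, Fam227a, Golim4, Siah3 and Hycc1, listed as Fam126a), against a mean of 3.67, and a share of 0.163 of length-matched sets held as many, so an excess was not detectable.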
